A study of Helianthus annuus with 142 samples.

How the data were processed

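Leaf RNA of sunflower, Helianthus annuus, was measured by RNA-seq in 142 libraries. Per the labels' protocols, 144 plants of 24 genotypes were grown singly in pots of 15 L of soil on a robotic phenotyping platform, under 2 levels of water supply, with 3 replicates in 3 blocks. Water was withheld from the stressed plants, and the platform replaced what the control plants lost. The leaves of a stressed plant and of a control plant were harvested together once the fraction of transpirable soil water (FTSW) of the stressed pot had fallen to 0.1. That fraction is the part of the soil water available to the plant that is still left. The protocol text also names plants of another genotype, XRQ, as those retained for its study, and may have been written for that study, so how far its harvest rule holds for these plants rests on the labels alone. Per the labels' protocols, total RNA was made into oriented TruSeq libraries and sequenced on an Illumina HiSeq instrument as paired reads of 100 bp.

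The authors deposited a table of read counts per gene for all 142 libraries, with gene positions per the file headers, and a second table after their own filtering. The submitters' processing notes name edgeR 3.16.5 and R 3.3.3 without saying what each was used for. The aligner, the counting tool, the genome build and the version of the gene models are not given in the sources used here. Gene identifiers and sequence names start with HanXRQ in the deposited tables. The values of the count table are whole numbers with a different total in each library. The values of the table after filtering are CPM in the deposited file, that is, counts scaled to a common library total, since the columns sum to between 999988 and 1000065, and it holds 30831 genes and 140 libraries, without SF009 stress replicate 1 and SF326 control replicate 3. It was used only to set the genes and libraries of 1 alternative, which was run on the raw counts. How the authors chose those genes and libraries is not given in the sources used here. Columns of stressed plants carry the genotype and the replicate number alone, and columns of control plants also carry the mark ctrl; each column was tied to the sample whose title has the same genotype, water supply and number.

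The gene identifiers were looked up in a table of 83308 RefSeq genes of the assembly HanXRQr2.0-SUNRISE, and 0 of them matched. No gene therefore has a symbol or a description here. The 32 gene lists fixed in advance (dehydrins, abscisic acid synthesis, photosystems, heat shock proteins and others) depended on descriptions and 0 of them could be run. The rule for named genes, also fixed in advance, then allowed only the 2 largest rises and the 2 largest falls in the average drought test, among genes with a mean log2 CPM of at least 1 and the same direction in all 24 genotypes.

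Of the 58050 genes in the count table, 17 are marked as ribosomal RNA (13 as 28S and 4 as 18S) and were left out before library sizes were computed; they took 0.00487% ± 0.0138 of the counts in control plants and 0.00140% ± 0.00274 in stressed plants (SD over 24 genotypes). SF109 control replicate 2 weighs heavily in the control mean, which was 0.00252% ± 0.00839 without it, and the share was higher under stress in 18 of 24 genotypes, against the order of the means. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (R 4.3.3) over the 48 groups of genotype by water supply, which left 36989 genes. Libraries were scaled by TMM. The normalization factors were 0.928 ± 0.0657 in 70 control libraries and 1.08 ± 0.0752 in 72 stress libraries (SD).

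Total counts per library ranged from 2796719 to 13765614, with a median of 6922010. The median was 7130247 over 46 libraries of lines and 6830270 over 96 libraries of hybrids. Libraries had no molecular identifiers, so counting error understates the error of a single library; the tests rest on the spread between plants.

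One mean per group was fitted by the quasi-likelihood method of edgeR (glmQLFit, robust), and contrasts were tested with its F-test at a Benjamini-Hochberg adjusted p of 0.05. The contrasts were stress against control averaged over the 24 genotypes with equal weight, stress against control in each genotype, the interaction of genotype and water supply, differences between genotypes averaged over water supply, the mean of 16 hybrids against the mean of 8 lines, the drought response of hybrids against that of lines, each hybrid against the mean of its 2 labelled parents on the log scale, and, among hybrids, the effects of the first-named parent, the second-named parent and their combination. Contrasts of some of the groups were computed from the libraries of those groups with the shared dispersions. Over 400 genes the log10 p of the average drought test matched glmQLFTest to a difference of 0, and that of a mid-parent test to within 0.00015. The SF342 control group has 1 library, which is assumed to vary like the other groups. Standard errors of log2 fold changes were obtained from the fold change and its F statistic.

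The size of a genotype's drought response was summarised as the slope, through the origin, of its log2 fold changes on the mean of the other genotypes, over genes called by the average drought test. Slopes of 16 hybrids and 8 lines were compared by a two-sided exact permutation test over all 735471 splits. Hybrids share parents, so these genotypes are not independent. Organelle shares were compared by permutation tests with 100000 resamples. Genes of a single parent had at least 5 CPM in every library of one parent and under 0.1 CPM in every library of the other; their level in the hybrid was divided by that in the expressing parent, for combinations with at least 10 such genes.

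As a check of the labels, 2916 genes near 0 in some libraries and expressed in others (a low quantile under 0.2 CPM and a high quantile over 4 CPM) were called on above 1 CPM. The agreement of a library with a genotype is the mean percentage of these genes in the same state as in the genotype's other libraries.

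Alternatives set before the data were examined were scaling by RLE, no low-count filter, the genes and libraries of the authors' filtered table, limma voom (limma), the DESeq2 Wald test (DESeq2 1.42.0), a test against a fold change of 1.5, each genotype fitted alone, a mid-parent on the linear scale, the replicate number as a block, pairs of genotype and replicate number as blocks, each replicate number left out, and SF342 left out. The mid-parent on the linear scale was tested with a Wald test on the edgeR fit in place of the F-test. Scaling by library totals (set in advance only for the level of genes of one parent in the hybrid), leaving out 15 libraries doubted in the check of labels, exchanging the labels of SF092_SF317 stress replicate 3 and SF326 stress replicate 3, the median score of the stressed plants in place of the slope, and, for the shares of organelle and ribosomal RNA counts, leaving out SF109 control replicate 2 were added after seeing the data. Regrouped samples were fitted with limma-trend.

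The tests were tried on simulated counts for 8000 genes, with 200 changed genes in each comparison. Counts were drawn with the mean of each gene over all real libraries and with the real library sizes. For the average drought effect, edgeR recovered 93% of genes changed 1.5-fold and 95% of those changed 2-fold. For drought in 1 genotype it recovered 34% at 2-fold and 75% at 4-fold, for hybrids against lines 81% at 1.5-fold and 94% at 2-fold, for the drought response of hybrids against lines 50% and 76% at the same folds, and for the first-named parent 88% at 2-fold and 97% at 4-fold. Unchanged genes made up 6.99%, 4.46%, 5.64%, 6.57% and 4.57% of the calls in these comparisons, in the same order, so false calls in 3 of the 5 lay somewhat above the nominal 5%. Apart from the changed genes, the simulated genotypes did not differ, and the response did not vary between plants across genes. The real genotypes and plants did both, so these rates may not hold for the real data. A gene changed in 1 hybrid alone counts as changed in every comparison whose average includes that hybrid; this definition was corrected after a first run of the simulation had counted such genes as unchanged for hybrids against lines and for the first-named parent. Replicates were also checked for libraries deposited more than once: over 141 pairs within groups, the chi-square per degree of freedom was at least 3.49, so all were kept.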

Results

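The leaf transcriptome of sunflower was compared between well-watered and droughted plants in 8 lines and 16 hybrids. Each hybrid is named after 2 of the lines. SF009, SF092, SF109 and SF193 stand first in the names, SF279, SF317, SF326 and SF342 stand second, and the hybrids cover each of the 16 combinations. These are called the first-named and second-named parents here, since the labels do not say which was the seed parent. Per the labels, control plants were kept at an FTSW of 1 and stressed plants were harvested at 0.1. Each of the 48 groups has 3 libraries, except the control group of SF342, which has 1. Each library came from its own plant, so p-values measure the spread between plants of a group. Total counts per library ran from 2796719 to 13765614. Genes are given by their identifiers, because the files do not pair these with symbols or functions.

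The design asks first which leaf genes change under water deficit across this range of genotypes. Averaged over the 24 genotypes, 11646 genes rose and 12095 fell among 36989 tested (edgeR quasi-likelihood F-test, adjusted p under 0.05). With TMM scaling, genes that fell moved further than genes that rose. The median log2 fold change was -0.77 among the fallen genes, of which 4674 (38.6%) changed more than 2-fold, and 0.52 among the risen genes, of which 2408 (20.7%) did. The direction held in all 24 genotypes for 3051 of the risen genes and 3400 of the fallen genes, and in at least 20 genotypes for 9072 and 9734. Tested against a fold change of 1.5, 3868 genes were higher and 6319 lower. Water supply was also the main axis of the data. The first principal component held 25.7% of the variance, while the next held 9.13%. Control libraries lay at one end of the first component, from -115 to -49.8. Stress libraries ran from -60.4 to 173, some of them near the middle, such as SF109 stress 1 at -1.74. The ranges overlapped little: 2 of 72 stress libraries fell within the range of the control libraries, and 3 of 70 control libraries within that of the stress libraries. The split of calls depends on the scaling: 49.1% of them were higher with TMM, 50.6% with RLE and 61.6% with library totals only, a scaling that moved the median log2 fold change of all genes from 0.03 to 0.22. The order of sizes depends on it too. Genes called with library totals had medians of 0.61 and -0.79, but the genes called with TMM had 0.73 and -0.56 on that scale, where the risen ones moved further.

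Changed genes were spread over the whole genome. On each of the 17 chromosomes, between 29.4% and 34% of the tested genes rose and between 30.7% and 34.2% fell. Risen and fallen genes were expressed at a similar level, with a median over genes of the mean log2 CPM of 3.26 and 3.03, while genes that were not called had a median of 0.12. Genes without a call thus tended to be expressed at a lower level. Whether depth kept them from a call was not tested.

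The 2 largest rises with the same direction in all 24 genotypes were in HanXRQChr14g0450531 and HanXRQChr11g0333201. HanXRQChr14g0450531, a gene model of 561 bp on the minus strand of chromosome 14 (141564248 to 141564808), went from 0.0801 ± 0.126 CPM in control plants to 98.6 ± 74.8 CPM in stressed plants (SD over genotype means, n = 24). It had 40 counts in all control libraries together and 61216 in the stress libraries, and its mean level was 1231 times higher. Its fitted log2 fold change was 10.05 (SE 0.42, edgeR adjusted p = 1.93e-43). HanXRQChr11g0333201, 7319 bp on the plus strand of chromosome 11 (60365061 to 60372379), went from 0.301 ± 0.548 to 91.3 ± 39.5 CPM, a ratio of 303, with a fitted log2 fold change of 9.45 (SE 0.32, edgeR adjusted p = 3.09e-53). The control plants held no counts of the first gene in 9 genotypes and none of the second in 5, so fitted folds in those genotypes depend on the prior count. The positions are those of the deposited table, whose genome build is not given in the sources used here, and neither exons nor untranslated regions were analysed.

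The 2 largest falls were in HanXRQChr04g0116941 and HanXRQChr13g0403071. HanXRQChr04g0116941, 11349 bp on the minus strand of chromosome 4 (139293889 to 139305237), went from 143 ± 63.1 CPM in control plants to 1.74 ± 3.55 CPM in stressed plants (SD over genotype means, n = 24). Its mean level was 82.0 times lower, and its log2 fold change was -7.99 (SE 0.23, edgeR adjusted p = 8.98e-58). HanXRQChr13g0403071, 366 bp on the minus strand of chromosome 13 (97608577 to 97608942), went from 247 ± 110 to 6.77 ± 12.3 CPM, which is 36.5 times lower, with a log2 fold change of -7.30 (SE 0.28, edgeR adjusted p = 1.94e-47). The fitted change of this gene ranged from -1.53 to -11.87 over the genotypes. Whether near-identical copies share reads with these 4 genes was not analysed here.

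**Figure D1:**
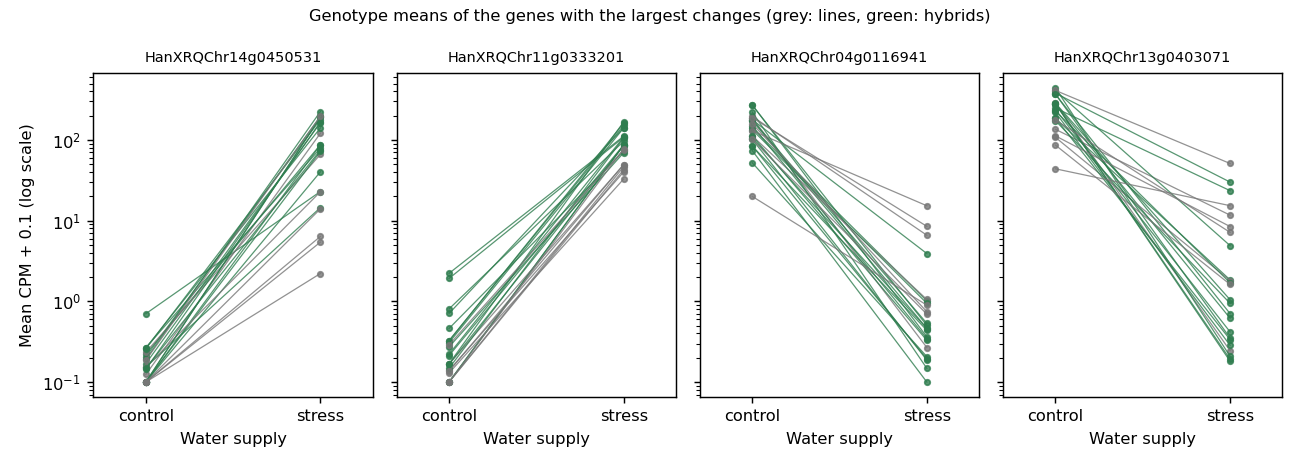
Mean CPM plus 0.1 (log axis) of the 4 named genes in control and stressed plants, with 1 line per genotype joining its means; lines in grey, hybrids in green. HanXRQChr14g0450531 and HanXRQChr11g0333201 rise from means of 0.0801 and 0.301 CPM to 98.6 and 91.3 CPM, and HanXRQChr04g0116941 and HanXRQChr13g0403071 fall from 143 and 247 CPM to 1.74 and 6.77 CPM.

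The shares of the 2 organelle genomes in the counts moved in opposite directions under drought. Genes on the mitochondrial sequence took 1.13% ± 0.234 of the counts in control plants and 1.32% ± 0.114 in stressed plants (SD over 24 genotypes), and their share was higher under stress in 22 of 24 genotypes (permutation test with 100000 resamples, adjusted p = 0.00288 over 3 shares). The exceptions were SF109, whose control replicate 2 had 4.05%, and SF092_SF317. The control libraries behind them also held the most ribosomal RNA of all libraries (0.169% in SF109 control replicate 2, 0.0732% and 0.0489% in SF092_SF317 control replicates 1 and 3). With SF109 control replicate 2 left out, the mitochondrial share of control plants was 1.08% ± 0.132, and the share was higher under stress in 23 of 24 genotypes. Of 27 mitochondrial genes tested one by one, 11 rose and 2 fell with TMM scaling. Their fallen share was below that of the other genes (Fisher's exact test, p = 0.0034), while the test of their risen share gave p = 0.305. Both tests count genes of 1 sequence as independent, so these p-values do not measure the spread between plants or genotypes. With library totals only, 17 rose, on a scale where the median of all genes rose by 0.22 and that of the mitochondrial genes by 0.37. Genes on the plastid sequence took 0.192% ± 0.0392 of the counts in control plants and 0.149% ± 0.0294 in stressed plants, and their share was higher under stress in only 3 of 24 genotypes (adjusted p = 0.00012). Only 8 plastid genes had enough counts for the edgeR test, of which 1 rose and 1 fell, and their median log2 fold change was -0.1 with TMM and 0.03 with library totals, so the lower share was not seen in these genes one by one. Ribosomal RNA did not differ in share by that test (adjusted p = 0.408). Hybrids and lines did not differ beyond their spread in any of the 3 shares (lowest adjusted p = 0.806).

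Before genotypes were compared, the libraries were checked against their labels with 2916 genes that are on in some libraries and off in others. In 135 of 142 libraries the state of these genes agreed best with the labelled genotype. The other 7 agreed better with another one. The library labelled SF092_SF317 stress replicate 3 shared the state of 50.9% of the genes with its labelled genotype and 82.8% with SF326, and the library labelled SF326 stress replicate 3 shared 47.5% with its own label and 77.2% with SF092_SF317. The library labelled SF009_SF279 control replicate 1 shared 60.4% with its label and 73.1% with SF009_SF326. The remaining 4 were labelled SF009, the line with the lowest mean agreement among its 6 libraries, 68.3%, against 75.2% to 89.99% in the other lines. Line SF092 differed from SF326 by 190 genes on in SF092 alone and 2 on in SF326 alone, while the other 27 pairs of lines differed by 287 to 1001 genes. All libraries stayed in the main tests under their labels, and counts that changed by over 1.5 times without these 7 libraries and the remaining ones labelled SF009 and SF092 are given beside the results.

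**Figure D2:**
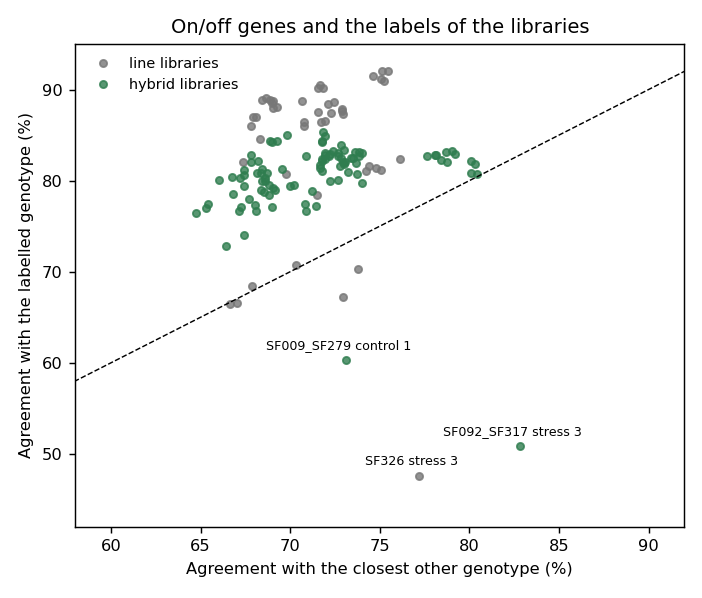
Each point is 1 of 142 libraries; the x axis is its percentage agreement over 2916 on/off genes with the closest other genotype, the y axis that with its labelled genotype, lines in grey, hybrids in green, and the dashed line marks equal agreement. The 7 libraries under the line include SF092_SF317 stress 3 at 50.9% and SF326 stress 3 at 47.5% agreement with their labels.

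The number of genes changed by drought within a genotype ranged widely. The median over genotypes was 10173 genes, and the counts ran from 720 in SF342, whose control group is a single library, to 14664 in SF092_SF342 (edgeR, adjusted p under 0.05). Hybrids had a median of 11969.5 drought genes (6488 to 14664, n = 16) and lines a median of 2413.5 (720 to 13902, n = 8). Among the lines, SF009 had 13902 and SF326 8630, both with libraries that agreed better with another genotype, and the other 6 had 720 to 4795. Without the doubted libraries the medians were 12744 in hybrids and 2580.5 in 6 lines. The response itself differed between genotypes for 5818 genes (interaction of genotype and water supply, 23 degrees of freedom). With each genotype fitted alone the median fell to 5250.5, with 10589.5 in hybrids and 434.5 in lines, and single genotypes moved far: SF009 had 5731 genes, while SF009_SF326 went from 8274 to 0 (edgeR; 7202 genes had an unadjusted p under 0.05). The median was 6473 without replicate 2. The interaction held 2640 genes with limma voom, and without any 1 replicate number it held between 1096 and 1480.

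**Figure D3:**
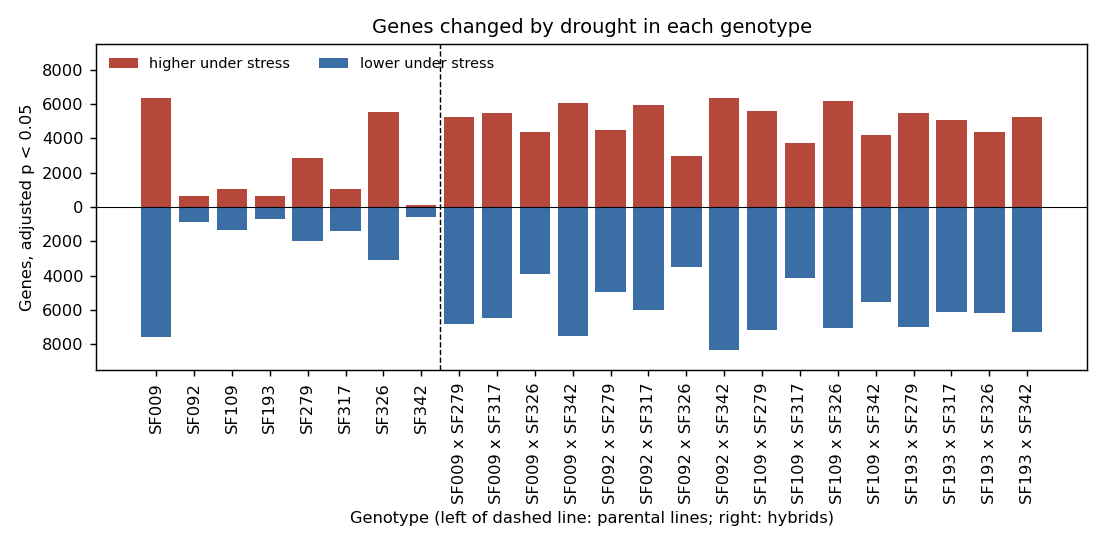
Number of genes changed by drought in each genotype (edgeR, adjusted p under 0.05), higher under stress above 0 and lower below 0; lines stand left of the dashed line and hybrids right of it. Line SF009 reaches 13902 genes in all, SF326 8630 and the other lines at most 4795, while hybrids run from 6488 to 14664.

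Drought changed expression more in hybrids than in lines. The slope of a genotype's log2 fold changes on the mean of the other genotypes was 1.14 ± 0.178 in 16 hybrids and 0.701 ± 0.234 in 8 lines (SD), a difference of 0.437 (two-sided exact permutation test over 735471 splits, p = 6.8e-05). Among the lines, SF009 stood highest with 1.16 and SF342 lowest with 0.344. Plants of a genotype also differed in their response. A score per stressed plant, the slope of its log2 differences from the control mean of its genotype on the mean change of the other genotypes, ran from 0.128 to 1.06 in 24 line plants (median 0.561) and from 0.287 to 1.22 in 48 hybrid plants (median 1.02). The difference between the lowest and the highest plant of a genotype had a median of 0.430 in lines and 0.241 in hybrids. It reached 0.869 in lines and 0.893 in hybrids, so a low slope can average strong and weak plants. With the median score of the 3 plants in place of the slope, hybrids had 1.02 ± 0.0840 and lines 0.538 ± 0.212 (SD; exact permutation p = 5.44e-06). The slope of the hybrid lay above that of both labelled parents in 15 of 16 crosses. It did not follow the mean slope of the parents (Pearson r = -0.135, permutation p = 0.615; Spearman rho = -0.115, permutation p = 0.675; n = 16; r = -0.0669 without SF009_SF326 and SF009_SF279, whose parental means lie farthest from the median). At the level of genes, 10730 had a different drought response in hybrids and lines (edgeR, adjusted p under 0.05). Of these, 4049 rose on average, and 93.2% of them changed by a larger amount in hybrids, with a median log2 fold change of 0.72 in hybrids and 0.33 in lines; 381 had opposite directions in the 2 kinds. A further 5749 fell on average, and 98.2% of them changed by a larger amount in hybrids, with medians of -1.42 and -0.61; 524 had opposite directions. The other 932 had no average drought call. Of these, 816 had opposite directions, with medians of -0.22 in hybrids and 0.2 in lines, and 44.6% changed by a larger amount in hybrids. These medians cover genes picked for a difference. Over all genes with an average drought call, whose average weighs 16 hybrids and 8 lines, the medians were closer, 0.57 in hybrids and 0.39 in lines for risen genes and -0.92 and -0.49 for fallen ones. The count of 10730 was 6473 without replicate 2, 4550 without replicate 3, which takes SF342 and its hybrids out, and 7035 with SF342 left out.

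**Figure D4:**
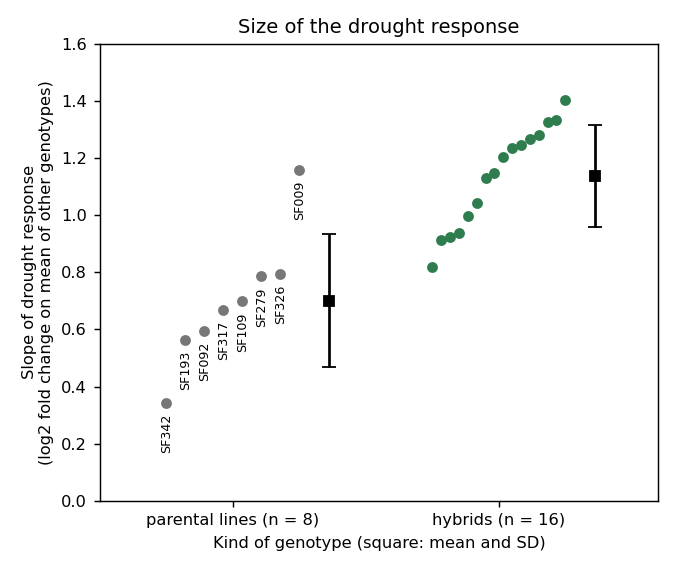
Slope of the drought response of each genotype, that is, of its log2 fold changes on the mean of the other genotypes (y axis), for 8 lines in grey and 16 hybrids in green, each sorted by value; squares and bars are mean and SD. The hybrids have a mean of 1.14 and the lines a mean of 0.701.

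Expression also differed between hybrids and lines when both levels of water supply were averaged. In hybrids 8395 genes were higher and 7008 lower than in lines (edgeR, adjusted p under 0.05), and against a fold change of 1.5 the counts were 1460 and 844. The count of lower genes was also set against other groupings of the genotypes. With limma-trend, 10 of 100 splits into 16 and 8 genotypes, the real one included, gave at least as many. Each line is a parent of equally many hybrids, so additive differences between lines on the log scale cancel in the real split. In other splits they need not cancel and can raise the counts, so these splits cannot decide on chance for the lower genes. No other split gave as many higher genes, though the other splits had a median of 5387 higher genes against 11553 in the real one. The median log2 difference was 0.43 among the higher genes and -0.37 among the lower ones. Of the higher genes, 2083 (24.8%) had a median under 0.1 CPM in at least 1 line, compared with 139 (1.98%) of the lower genes. Lines and hybrids were averaged on the log scale. There a gene off in 1 parent lies above the mean of its parents when the hybrid holds an intermediate level of it. Such genes can count as higher in hybrids though additive on the linear scale. This contrast was not run on that scale. Genes higher in hybrids tended to be genes that rose under drought: 4588 were called in both, where independent lists of these sizes would share 2643. In the same way 4563 genes were lower in hybrids and lower under drought, against 2292 for independent lists. The average over water supply includes the stressed plants. For the 4588 genes, the median log2 difference between hybrids and lines was 0.25 in control plants and 0.42 in stressed plants, and for the 4563 genes it was -0.16 and -0.66. The larger difference under stress is not general: over all 8395 higher genes it was 0.45 in control plants and 0.39 in stressed plants, and over the 2490 of them without a drought call 0.87 and 0.59. Over all 7008 lower genes it was -0.25 and -0.49, and over the 1186 of them without a drought call -0.39 and -0.34. The share of higher genes among these calls was 54.5% with TMM and 61.5% with library totals only.

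A hybrid was next compared with the mean of its 2 labelled parents, which asks whether expression is additive in the cross. On the log scale a median of 2483.5 genes per hybrid lay off the mid-parent in control plants (927 to 7834, n = 16) and 4051 in stressed plants (1225 to 11417). More genes lay above than below it in 16 of 16 hybrids in control plants and in 15 of 16 under stress. This direction did not hold with the parents averaged on the linear scale, where a Wald test took the place of the F-test. The medians fell to 410.5 and 2275.5 genes, and more lay above than below in only 4 and 2 of the 16 hybrids. The change of scale and the change of test were not separated. In a median of 41.7% of the log-scale calls in control plants, and 26.9% under stress, one of the parents had a median under 0.1 CPM. The medians were 1188 and 1957.5 without replicate 1, and 1469 and 1999 without replicate 2. With the labels of SF092_SF317 stress replicate 3 and SF326 stress replicate 3 exchanged, the median under stress was 6096.5. Without the doubted libraries the median under stress was 8058 over the 8 hybrids that kept both parents, which had a median of 5290 with all libraries.

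**Figure D5:**
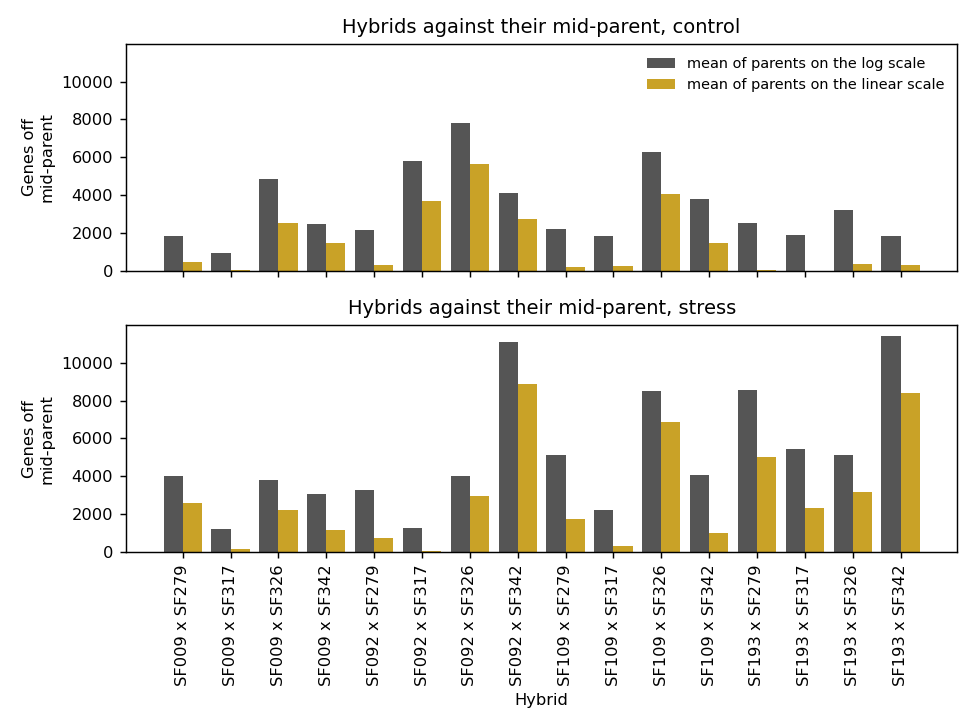
Number of genes off the mid-parent (y axis) in each of 16 hybrids, in control plants (top) and stressed plants (bottom), with the parents averaged on the log scale (grey, F-test) or on the linear scale (yellow, Wald test). The medians are 2483.5 and 410.5 genes in control plants and 4051 and 2275.5 under stress.

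Genes expressed in a single parent show what the hybrid inherits from each side. Their median level in the hybrid was 0.547 ± 0.0744 of the level in the expressing parent (SD over 28 combinations of hybrid and parent with at least 10 such genes), with a range of 0.379 to 0.758. The level was 0.548 ± 0.0757 for genes of the first-named parent (15 combinations) and 0.540 ± 0.0708 for genes of the second-named parent (13 combinations). The lowest value, 0.379, was for genes of SF317 in SF092_SF317, a group that includes the library that agreed best with SF326. The median level over combinations was 0.534 ± 0.198 without replicate 3 (31 combinations). With the labels of 2 libraries exchanged it was 0.546 ± 0.180 (29 combinations). The median thus held, but the spread was wider.

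Genotypes differed for most genes. Averaged over water supply, 32260 of 36989 genes differed between the 24 genotypes (edgeR, 23 degrees of freedom). Among the hybrids, 20114 genes had an effect of the first-named parent and 19674 one of the second-named parent (3 degrees of freedom each), and 13265 had both, where independent lists would share 10698. With limma-trend the 2 counts were 20500 and 20169. Hybrids moved at random to other places in the cross gave medians of 14403 and 14233. These placements keep the real differences between hybrids, including those that come from the parents. Their medians are thus not the counts to be expected without parent effects. The part of each count due to the parents was not separated. The particular combination of parents had an effect on 7311 genes (9 degrees of freedom), 6970 of which also had an effect of at least 1 parent. The count was 8787 without the doubted libraries and 8168 with the labels of 2 libraries exchanged. SF009_SF279, SF092_SF326 and SF109_SF326 held the most genes that neither labelled parent expressed. Whether such hybrids add to the count was not tested, nor whether chance can be excluded for it. Among the 27 mitochondrial genes, 8 had an effect of the first-named parent and 15 one of the second-named parent. Among 36954 nuclear genes, 20104 and 19657 did. The mitochondrial genes lie on 1 sequence and are not independent, and no difference between these shares was tested.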

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

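The tests of exchanged labels, of mixed RNA, of gene dose in SF092, of a close relation between SF092 and SF326, of genes kept in the hybrids of SF092, of the slope without the doubted libraries and of the median plant were chosen after the result was seen; the other tests in this part were set before it.

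Agreement with the labelled genotype was compared among the libraries of each genotype. Relative to the spread of their genotype, 6 libraries stood apart: SF009_SF279 control 1 (60.4%), SF092_SF317 stress 3 (50.9%), SF326 stress 3 (47.5%), SF193_SF342 control 2 (80.8%), SF092 stress 3 (80.7%) and SF193 stress 3 (82.3%). The last 3 still agreed best with their own label. SF193 stress 3 had a drought score of 0.828, against 0.333 and 0.163 in the other stressed plants of SF193. SF092 stress 3 had 0.801, against 0.380 and 0.323 in those of SF092. Agreement was taken over control and stress libraries together, so it may carry the drought response as well as the genotype, which was not tested. SF193_SF342 control 2 lay close to the others of its genotype, which had 81.9% to 82.5%. The mitochondrial share of line SF109 (1.59%) stood apart from those of the other lines; its control replicate 2 had 4.05% and, with 2796719 counts, the lowest depth of all libraries. In 27 groups tested, 7 values stood apart in this way, where chance gives about 1 in 20.

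The library labelled SF092_SF317 stress replicate 3 shares the on/off state of 82.8% of genes with SF326, and the library labelled SF326 stress replicate 3 shares 77.2% with SF092_SF317. RNA mixed from both plants is argued against, because only 2.13% of the genes expressed by SF317 and not by SF092 were on in the library labelled SF092_SF317. A candidate explanation is an exchange of the 2 labels. The agreement of each library with the genotype of the other label was not below that of the label's remaining libraries, which it exceeded by 2.08 and by 1.54 percentage points. The means of the remaining libraries include the doubted library of that label with a larger weight, which lowers them. The excess itself is therefore not read as evidence. Fitted under each other's label, 11474 genes rose and 12218 fell under drought, the interaction of genotype and water supply held 7007 genes, and the median number of genes off the mid-parent under stress was 6096.5, against 4051 as labelled. The other counts run moved by less than 1.5 times.

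Libraries labelled as line SF092 show nearly every gene of line SF326, and 190 genes beyond that. A pair of closely related inbred lines would each hold some genes the other lacks. Here 1.04% of the genes on in only one of them belonged to SF326. In the other 27 pairs of lines, the line with fewer such genes held 19.3% to 48.9%. A limit of 10% was set for a close relation after these counts were seen. The share restates the pattern, so it decides nothing about a close relation. A candidate explanation is that the plants sampled as SF092 came from a cross of SF092 with SF326 or a mixture with it. Of 27 genes that the line shows and that its hybrids with SF279, SF317 and SF342 lack, 96.3% were on in SF326. Since 97.9% of all genes shown by the line were on in SF326, that share needs a base rate: among 82 genes of the line that are off in SF279, SF317 and SF342, 95.8% of the 24 lacking in those hybrids and 53.4% of the 58 others were on in SF326 (Fisher's exact test, p = 0.00011). The genes on in SF092 and off in SF326 stood at a median of 0.575 of their level in other lines expressing them, against 0.883 to 1.16 for 35 pairs in which another line expressed the genes. Genes of SF092 that are off in a line other than SF326 also stood low, at 0.761 to 0.838 over 5 pairs, so part of the lower level holds for SF092 in general. A mixture of RNA and a cross remain open alike, and no difference named by the design bears on this.

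The drought response differed between genotypes for 5818 genes and between hybrids and lines for 10730 genes, by tests of the interaction itself, and the slope of the response was 0.437 higher in hybrids. Wrong or mixed line libraries as the whole reason are argued against, since the difference in slope was 0.545 (exact permutation p = 1.34e-05) without the 15 doubted libraries. Depth as the whole reason is argued against too: with every library thinned to 2796719 counts the difference was 0.477, against 0.476 from the same group means at full depth. What stays open is the kind of genotype itself, and whatever goes with it in this experiment, such as plant size or the day on which a pot reached its FTSW, for which no value per plant was used here. Unequal drying of single plants stays open too: scores of stressed plants ran from 0.128 to 1.06 in lines and from 0.287 to 1.22 in hybrids, and the difference was 0.482 with the median plant of each genotype in place of the slope, which sets aside a single weak plant but not 2 of 3. Under that reading, a larger response of hybrids may be biological, but this was found and tested on the same data.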

How the results depend on the processing

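Scaling by library totals (except for the level of genes of one parent in the hybrid, where it was set in advance), leaving out the doubted libraries, exchanging the labels of 2 libraries, taking the median plant of a genotype and leaving out SF109 control replicate 2 were chosen after seeing the data. Of 234 values under an alternative, 212 stayed within 1.5 times for a count, within 1 SD for a level, or with the same sign and on the same side of the threshold for a difference. Most are counts, which have no sign to reverse. Directions outside this list did turn: with the mid-parent on the linear scale and its Wald test, hybrids with more genes above than below it went from 16 to 4 in control plants and from 15 to 2 under stress, and the higher share of drought calls went from 49.1% to 61.6% with library totals. The difference in slope kept p under 0.05 under all 12 alternatives run, and the changes of the 4 named genes kept their direction and call under all 9. With the DESeq2 Wald test, 14103 genes rose and 13283 fell under drought, sharing 11634 and 11784 with the edgeR calls, so 11634 of 11646 and 11784 of 12095 genes were called by both.

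Against a fold change of 1.5, the genes risen and fallen under drought were 3868 and 6319, and those higher and lower in hybrids 1460 and 844, because the test itself asks for more. Each genotype fitted alone gave a median of 5250.5 drought genes, with fewer residual degrees of freedom. The interaction of genotype and water supply held 2640 genes with limma voom; the cause was not tested. With the labels of SF092_SF317 stress replicate 3 and SF326 stress replicate 3 exchanged, 6096.5 genes lay off the mid-parent under stress (median over hybrids); the cause was not tested. With SF342 and its hybrids left out, the response differed between hybrids and lines for 7035 genes, from fewer samples. With the mid-parent on the linear scale, 410.5 genes lay off it in control plants and 2275.5 under stress, and without the doubted libraries 8058 under stress, over the 8 hybrids whose parents both stayed (5290 in the same 8 with all libraries; the cause was not tested). Without replicate 1, 2 or 3, from fewer libraries, the median number of drought genes was 6473 to 7594, the interaction held 1096 to 1480 genes, the difference in response between hybrids and lines 4550 to 7982, and the mid-parent medians were 1188 to 1763 in control plants and 1957.5 to 3715 under stress.

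The labels do not say what a replicate number marks. Plants of a genotype with the same number deviated together in 38 of 69 pairs at a correlation above 0.1 (mean 0.114, against -0.0559 for other numbers), and 46 of the 69 correlated best with their own number, where 23 would by chance. This is a hint from the data that the numbers carry something within a genotype; not every pair passed 0.1, so by the rule set in advance the number was not taken to pair them. With the replicate number as a block, 11641 genes rose and 12109 fell. With pairs of genotype and number as a replicate block, 11355 rose and 12191 fell, and the interaction held 3717 genes. No other count run moved by over 1.5 times with either block; with pairs as blocks only the counts of the average drought test, of drought genes per genotype and of both interactions were run.

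Depth may limit the low end, which was not tested: genes without a drought call had a median of 0.12 mean log2 CPM. Thinning every library to the lowest total moved the difference in slope from 0.476 to 0.477. No gene list was run.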

Other observations

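The test of neighbouring genes was set before its result was seen. Genes that changed together under drought tended to sit side by side. Of 36632 pairs of adjacent tested genes, 4205 rose together, 1.14 times the mean of 1000 shuffles of the calls within chromosomes (3685), and 4399 fell together, 1.12 times the mean of the shuffles (3926). Both counts lay above all 1000 shuffles. The same held for genes with an effect of the first-named parent (1.08), of the second-named parent (1.09) and of the parent combination (1.46). A longer list leaves the ratio less room to rise, so these ratios are not ranked. One hypothesis is that position on the chromosome is shared by genes that change together, which may reflect tandem copies, shared reads between copies or linked variants; these were not told apart.

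Most genes switched on in a hybrid are on in a labelled parent. In 13 of 16 hybrids at most 2 genes with a median of at least 5 CPM were under 0.1 CPM in every library of both parents. The exceptions were SF092_SF326 with 10 such genes, SF109_SF326 with 9 and SF009_SF279 with 8. SF092_SF326 also had 13 genes under 0.1 CPM that both labelled parents expressed, and the other 15 hybrids had 0. A further 17 genes were on in line SF279 and in no other line but SF009, where 2 of them were on. Of these 17, 9 were on in SF009_SF326, 9 in SF092_SF326, 9 in SF109_SF326 and 0 in SF193_SF326. Hybrids with SF317 and SF342 had 0 to 2 of them on. The reason was not tested. Genes expressed in SF009 and not in SF279 were on in 67.2% of cases in SF009_SF279, against 97.8% to 100% for the genes of SF009 in its other hybrids. For genes of SF092 the share was 75% to 78.7% in its hybrids with SF279, SF317 and SF342.

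Each count of genes was also set against other splits of the same libraries or genotypes, with 100 splits in each case, the real one included, fitted with limma-trend. Only the real split reached its value for genes risen under drought (14272, highest other 4876), fallen under drought (14269 and 3665), changed in a genotype (median 10238.5 and 14.5), differing in response between genotypes (4935 and 34), differing between genotypes (31730 and 58), off the mid-parent in control plants (2410 and 6) and under stress (4205.5 and 2.5), higher in hybrids (11553 and 8637), differing in response between hybrids and lines (12206 and 6541), and affected by the first-named parent (20500 and 19100) or the second-named parent (20169 and 18151). Chance can be excluded at 1 of 100 for these, apart from the difference in response between genotypes and the mid-parent counts. The splits for those moved libraries between genotypes, so all differences between genotypes entered the spread within groups. That fixes low counts in the other splits in advance, so chance was not tested for them. For the parent effects the other splits had medians of 14403 and 14233 genes. Those splits keep the real differences between hybrids, so these medians are not counts to be expected without parent effects. For the genes lower in hybrids, 10 of 100 splits of the genotypes gave as many (7789, highest other 9413). Differences between lines that are additive on the log scale cancel in the real split and need not cancel in the others. These splits therefore cannot decide whether chance can be excluded for the lower genes. For the effect of the parent combination all 100 splits gave as many genes or more (6568, highest other 23242). A split that moves hybrids to other places in the cross turns parent effects into effects of the combination, which fixes that outcome in advance, so whether chance can be excluded was not tested for this effect.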
